A study of Homo sapiens with 30 samples.

How the data were processed

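RNA was measured on 30 whole-transcript expression arrays, 1 per sorted cell fraction. Per the labels' protocols, cells from primary cutaneous squamous cell carcinomas, a cancer of skin keratinocytes, were sorted by the surface protein CD133, and total RNA was extracted with Trizol. The RNA was amplified with a NuGEN Pico kit, which is made for small amounts of RNA, and labelled with biotin. The labels' protocols also describe labelling from a fixed larger amount of RNA, so the amount that entered each array is not settled. The deposited values are log2 expression values, and the submitters' processing notes name RMA and Partek without versions. RMA combines background correction, quantile normalization and summarisation of probes. The deposited log2 values ran from 1.54 to 13.66, and array medians lay between 4.37 and 4.52. A second deposited table held 4428 of the same probe sets with log2 values identical to the first, with a largest difference of 0. The table's 4201 lowest-numbered probe sets precede every annotated one, so it added no measurement and was not used further. Arrays give no read depth, and the number of arrays limits the precision.

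The first table held 33297 probe sets. The platform annotation gave 1 gene symbol for 19460 of them, several for 1754 and none for 12083. Symbols were updated through Entrez identifiers with the RefSeq gene table of GRCh38.p14, which matched 19405 probe sets, and no coordinates from it are printed. Probe sets with several symbols or none were not named, and 24 probe sets of XIST, TSIX or Y-linked genes were left out. The remaining 19436 probe sets covered 18394 genes, of which 768 had several probe sets; the probe set with the highest mean over all samples then stood for the gene. Dim probe sets were not filtered out.

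The 30 samples form 15 CD133-positive and 15 CD133-negative samples by the labelled CD133 status. The sample titles carry 1 number for each pair, and the tumours are numbered here from 1 to 15. The labels describe the fractions as sorted from primary tumours, and samples with the same title number were taken as fractions of the same tumour. Deviations from the group means correlated with r from -0.32 to 0.57 between samples of the same number, with a median of 0.10, and 7 of 15 pairs were over 0.1. Samples of different numbers had a mean r of -0.01. In 3 of 15 pairs each sample was the other's best match. The pairing therefore comes from the titles, and the values themselves give it little and uneven weight.

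Differences were tested with limma 3.58.1 in R 4.3.3 as CD133-positive minus CD133-negative, with tumour as a fixed block and moderated variances, two-sided. P-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. For PROM1 and for list means, all sign flips of the 15 paired differences gave an exact permutation p. Gene lists were 29 sets of 595 symbols, of which 542 were measured, and 17 genes stood in more than 1 list. A symbol missing from the annotation was replaced by a gene listing it as a synonym and counted as measured. LAMA4, TANK and MS4A4A thus stood for LAMA3, TRAF2 and MS4A7 in the basal keratinocyte, NF-kB component and myeloid lists. Lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 29 lists, with an estimated correlation and limma's fry as alternatives. A list's shift is the mean of its paired differences minus the mean over all genes. Members were also adjusted over the list alone. The relation of NOTCH1 or CHUK with the NF-kB target list used Pearson's r and Spearman's rho with 100000 permutations, as a family of 4 relations. The design, the lists and the rule for naming genes were set before the data were examined. That rule takes PROM1, NOTCH1, NFKB1, RELA, CHUK and IKBKB always, up to 10 genes per direction that pass the threshold and move the same way in at least 12 tumours, filled up by smallest p where fewer pass, and up to 4 members of each list by smallest p.

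The gene test was tested on simulated data for the 18394 genes in 15 tumours. With the tumours' own deviations as noise it recovered 39 of 50 genes changed by 0.5 log2, 47 of 50 changed by 1, and 50 of 50 changed by 2, with 6 false calls. Each changed gene was shifted equally in all 15 tumours, so these counts do not hold for changes present in a few tumours. The genes of all sizes, with 50 more changed by 3 log2, were put into the same data and adjusted together. Many true changes make the adjusted threshold easier to reach, so the counts do not give the power where few genes change. In the same noise camera with its preset correlation called 8 of 28 lists that had not been shifted, against 0 of 28 in independent noise. The sign-flip test gave an unadjusted p under 0.05 for 3 of 28 such lists in each kind of noise.

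After the data were examined, analyses without 4 tumours whose CD133-positive array had a compressed range (SD under 1.6), with near-identical tumours counted once (root mean square difference under 0.3 log2), and with both were added, as was the sign-flip test of lists. Alternatives set beforehand covered no block, a random block with a correlation of 0.21, quantile normalization on top, centring each array on its median, the mean of all probe sets, a filter on dim genes that kept 9197, array quality weights from 0.31 to 1.95, leaving out each tumour, unmoderated and trend-robust tests, other thresholds and 33273 probe sets tested singly. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.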

Results

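Gene expression was measured in CD133-positive and CD133-negative cells sorted from 15 primary cutaneous squamous cell carcinomas, giving 15 arrays per fraction. CD133, encoded by PROM1, is a membrane glycoprotein that is widely used to enrich stem-like tumour cells, and the series title links Notch1 and NF-kB to the CD133-positive cells. The comparison asks which genes differ between both fractions of the same tumour. Values are deposited RMA log2 values, and differences are CD133-positive minus CD133-negative.

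The arrays were not of equal quality. The CD133-positive arrays of tumours 4, 5, 6 and 12 had a compressed range, with an SD over all probe sets of 1.44 to 1.53, against 1.66 to 1.75 on the other 26 arrays. On these 4 arrays the basal keratin KRT5 lay between 4.95 and 6.35, against 7.37 to 11.51 elsewhere, and the mean of the ribosomal protein list lay between 5.97 and 6.38, against 7.20 to 9.90. In addition, 5 of the 435 pairs of arrays were near-identical, with a root mean square difference of 0.206 to 0.270 log2 where the next pair differed by 0.363. They joined tumours 3 and 8 in both fractions, tumours 7 and 9 in both fractions, and tumours 11 and 14 in the CD133-positive fraction. These arrays carry different tumour numbers and their values are not identical, so all 15 tumours were tested as planned, and values with such tumours averaged and counted once (12 tumours) are given where counting once changed a call.

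**Figure D1:**
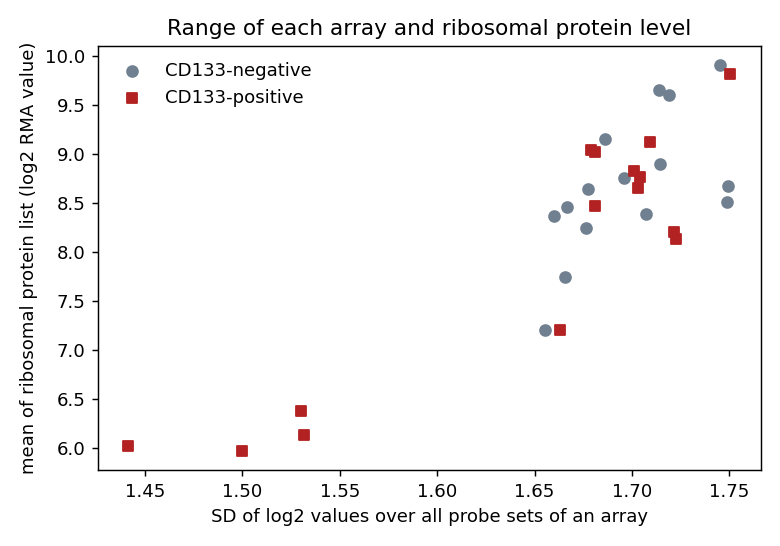
Mean log2 level of the ribosomal protein list (vertical axis) against the SD of log2 values over all probe sets of the array (horizontal axis); each point is 1 array, with squares for CD133-positive and circles for CD133-negative samples. The 4 arrays with an SD of 1.44 to 1.53 are all CD133-positive and have list means of 5.97 to 6.38.

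PROM1 separated the fractions clearly in 3 of the 15 tumours. Its level was 8.59 in the CD133-positive and 3.11 in the CD133-negative sample of tumour 1, 6.12 and 3.22 in tumour 9, and 4.99 and 3.35 in tumour 7, and tumours 7 and 9 are joined by near-identical arrays. In the other 12 tumours the difference ran from -0.18 to 0.39, and their CD133-positive samples lay between 3.02 and 3.82, in the range of the CD133-negative samples (3.02 to 3.62) or just above it. Over all tumours PROM1 was higher by 0.78 ± 1.53 (SD, n = 15), with a median difference of 0.26, and was higher in 12 of 15. All sign flips of the 15 paired differences gave an exact two-sided p of 0.00543, limma's moderated paired test gave p = 0.0441, and its adjusted p over all genes was 0.463. With near-identical tumours counted once, limma's p was 0.0742, and without tumour 4, 5, 7, 9 or 12 it was 0.0511, 0.0507, 0.0758, 0.0952 and 0.0510. Without tumour 1 the difference was 0.44. Only 1 probe set, 8099476, measured PROM1.

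**Figure D2:**
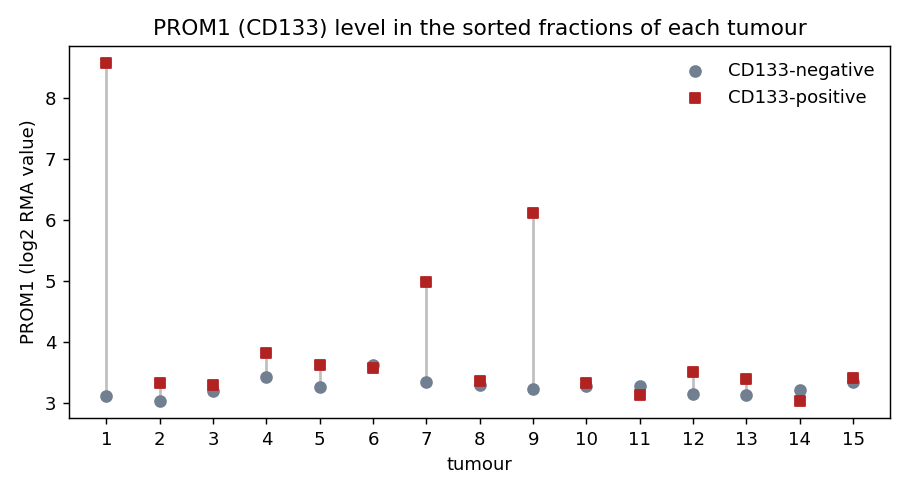
PROM1 level (log2 RMA value, vertical axis) in the CD133-negative (circles) and CD133-positive (squares) sample of each of 15 tumours (horizontal axis), with a grey line joining both samples of a tumour. Tumours 1, 7 and 9 differ by more than 1 log2, and the other 12 differ by -0.18 to 0.39.

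Across all genes, the 3 transcripts with the smallest p, UQCRQ, SNORA21 and COX4I1, had lower values in the CD133-positive cells. UQCRQ, a subunit of respiratory complex III, differed by -2.12 ± 1.40 (SD of 15 paired differences), and COX4I1, a subunit of cytochrome c oxidase, by -0.53 ± 0.35, each lower in 14 of 15 tumours. SNORA21, a small nucleolar RNA that guides pseudouridylation of ribosomal RNA, differed by -3.15 ± 2.18, and S100A10, the partner of annexin A2, by -2.16 ± 1.69, each lower in 14 of 15. HBB, the beta chain of haemoglobin, differed by -3.45 ± 2.92 and the delta chain HBD by -0.93 ± 0.70, also each lower in 14 of 15. SNORA71D differed by -2.12, SLIRP, a mitochondrial RNA-binding protein, by -2.79, ROMO1, a mitochondrial membrane protein, by -1.18, and BEX3 by -0.42.

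In the other direction the leading genes had small differences. MRPL19, a mitochondrial ribosomal protein, was at 4.11 in CD133-positive and 3.75 in CD133-negative cells, a difference of 0.37 ± 0.22 with a higher value in 14 of 15 tumours. GPR137B differed by 0.32, the choline transporter-like gene SLC44A4 by 0.28, HELT by 0.34, ALMS1, the centrosomal gene of Alström syndrome, by 0.25, and TRAM2 by 0.26, each higher in 14 of 15. The long non-coding RNAs SSTR5-AS1 and VHRT differed by 0.43 and 0.28, KCTD13 by 0.42 and SLFN14 by 0.34. SLFN14, ALMS1, GPR137B, MRPL19 and TRAM2 were at 3.18, 3.37, 3.74, 3.75 and 4.17 in CD133-negative cells. These levels lay below the gene median of 4.58 there, the other genes of this direction lay above it, and no background level was estimated here.

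None of these genes passed the threshold with the fixed tumour block. With limma's moderated paired test, 0 genes were higher and 0 lower at an adjusted p under 0.05; the smallest adjusted p was 0.0828, reached by UQCRQ and SNORA21, and 3 genes were under 0.1, the third being COX4I1. At an unadjusted p under 0.05, limma gave 1588 genes higher and 392 lower among 18394, where 920 in all would be under it by chance, and the unmoderated paired test and the trend-robust limma test also passed 0 genes. Without the 4 tumours with a compressed range these counts were 536 higher and 421 lower, and HBD alone passed (limma adjusted p = 0.0200 with n = 11 tumours). With no replicate block, limma passed 5 genes: S100A10, SNORA21, SNORD33, HBD and MRPL19. With tumour as a random block limma passed 11: these 5 and UQCRQ, COX4I1, BEX3, HBB, SPRR1B and RPL32 (adjusted p from 0.00500 to 0.0427). Leaving out 1 tumour passed COX4I1 without tumour 2, UQCRQ without tumour 4, 5 or 7, SNORA21 without tumour 4, HBD without tumour 6, and BEX3 and S100A10 without tumour 15 (limma adjusted p from 0.000510 to 0.0388).

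The genes of the Notch pathway, which signals between neighbouring cells, did not pass as a list. Of 33 measured members 30 had a positive mean difference, with a median of 0.12, where 73.3% of all genes were positive with a median of 0.07, and 4 had an unadjusted p under 0.05. NOTCH1, the receptor in the series title, was at 5.69 ± 0.38 in CD133-positive and 5.43 ± 0.37 in CD133-negative cells (SD, n = 15), a difference of 0.26 with a higher value in 9 of 15 tumours and a limma adjusted p of 0.446. Its 3 largest differences, 1.04, 0.83 and 0.71, were in tumours 6, 5 and 12, whose CD133-positive arrays had a compressed range, and without the 4 such tumours NOTCH1 differed by 0.12, HES4 by 0.20, HES5 by 0.12 and NRARP by 0.14. CTBP1, a corepressor, differed by 0.26, POFUT1, which adds fucose to Notch receptors, by 0.17, and NOTCH3 by 0.16. Among the Notch target genes HES4, HES5 and NRARP differed by 0.31, 0.29 and 0.23. HES1, another target gene, differed by 0.21, and by 0.33 without the 4 tumours with a compressed range. There CTBP1, POFUT1 and NOTCH3 differed by 0.23, 0.17 and 0.14. Limma's camera gave adjusted p = 0.0873 for the pathway and 0.424 for the 16 target genes, and adjusted p = 0.745 and 0.898 with an estimated correlation.

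NF-kB components and targets showed no common direction. CHUK, the kinase IKK-alpha, was at 2.91 ± 0.33 in CD133-positive and 2.58 ± 0.13 in CD133-negative cells, 0.33 higher, with a higher value in 12 of 15 tumours. Both means lay below the gene median of 4.58 in CD133-negative cells, and no background level was estimated here. Whether CHUK's passes and correlation rest on values above background was therefore not tested. TAB3, an adaptor of the TAK1 kinase, differed by 0.25, or by 0.16 without the 4 tumours with a compressed range. NFKB1 and RELA, the p50 precursor and the p65 subunit, differed by -0.01 each, and the kinase IKBKB by 0.10. In the NF-kB component list IL1R1 differed by -0.21 and TRADD by 0.16. Among 36 measured NF-kB targets 19 lay above and 17 below 0, where 73.3% of all genes lay above 0. The targets with the smallest p were XIAP at 0.26, CCL5 at 0.27, MMP9 at 0.17 and BIRC2 at 0.20. Limma's camera gave adjusted p = 0.877 for the 31 components and 0.121 for the targets, in the lower direction for both, and adjusted p = 0.931 and 0.287 with an estimated correlation. The targets passed camera without tumour 3 (limma adjusted p = 0.0486), with near-identical tumours counted once (0.0319) and with dim genes filtered out (0.0137). Their shift had the other sign without the 4 tumours with a compressed range (0.03, limma adjusted p = 0.959) and with array weights (0.03, limma adjusted p = 0.980). Without those tumours TRADD differed by 0.06, MMP9 by 0.11, IKBKB by 0.18, NFKB1 by -0.03 and RELA by 0.03. The component list's mean relative to all genes, 0.01, had the other sign than camera's direction, and the target list's median was 0.00 where its mean relative to all genes was -0.05.

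Adjusted over the list alone, 0 genes passed in any of the 4 Notch and NF-kB lists by limma's moderated paired test, as over all genes. At an unadjusted p under 0.05 there were 4 of 33 in the Notch pathway and 4 of 16 among Notch targets. There were 2 of 31 among NF-kB components and 1 of 36 among NF-kB targets, all higher. Over all genes 1980 of 18394 were under it, 1588 higher and 392 lower, so a higher direction is not particular to these lists. Without the 4 tumours with a compressed range 536 genes were higher and 421 lower. The smallest limma adjusted p over the list alone were 0.0582 for CTBP1, 0.0771 for HES4, HES5 and NRARP, 0.0917 for CHUK and TAB3, and 0.434 for XIAP. CTBP1 passed without tumour 4 or 9 (limma adjusted p = 0.00730 and 0.0412), HES4 without tumour 1, 8 or 10 (0.0400, 0.0408 and 0.0312), HES5 and NOTCH3 without tumour 8 (0.0408), CHUK without tumour 9 (0.0473), and XIAP without tumour 14 (0.0409). With a random block in place of the fixed one, CHUK and TAB3 passed over the list alone (limma adjusted p = 0.0164 and 0.0336), and with no replicate block CHUK did (0.0334). With quantile normalization on top, HES4, HES5, NRARP and NOTCH3 passed with a limma adjusted p of 0.0460 each.

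The level of NOTCH1 was set against the mean of the NF-kB target list across tumours. The paired difference of NOTCH1 had r = -0.45 with that of the list over 15 tumours (permutation p = 0.0979, adjusted over 4 relations 0.196; rho = -0.48, permutation p = 0.0770, adjusted 0.154), and r = -0.47 without the 2 tumours farthest from the median of NOTCH1. With the median of the list in place of its mean, r had the other sign, at 0.45 (permutation p = 0.0955). Within CD133-positive samples r was -0.70 (permutation p = 0.0040, adjusted 0.0160; rho = -0.55, permutation p = 0.0350, adjusted 0.140). That relation rests on a few samples: without the 2 farthest tumours r was -0.45 (permutation p = 0.122), and without the 4 tumours with a compressed range it was 0.22 (permutation p = 0.511, n = 11). Given the mean of the reference genes, the partial correlation was -0.14 (permutation p = 0.624). Within CD133-negative samples r was -0.36 (permutation p = 0.190, adjusted 0.253; rho = -0.20, permutation p = 0.483, adjusted 0.643), -0.47 without the 2 farthest, and -0.55 without tumour 11 (permutation p = 0.0403). For the paired difference of CHUK r was -0.17 (permutation p = 0.555, adjusted 0.555; rho = -0.05, permutation p = 0.872, adjusted 0.872), and 0.16 without the 2 farthest.

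Several abundant keratinocyte genes had lower values in CD133-positive cells. KRT5 and KRT14, the keratins of the basal layer, were at 8.63 and 8.96 in CD133-positive and at 9.94 and 9.93 in CD133-negative cells, lower in 9 and 11 of 15 tumours. Without the 4 tumours with a compressed range KRT5 differed by -0.25 in place of -1.31, KRT14 by -0.49 in place of -0.96, MMP10 by -0.22 and TWIST2 by 0.10. ITGB1, an integrin of basal cells, differed by -0.65. Of the cornified envelope precursors, SPRR1B fell by 0.68 and SPRR2A by 1.12, each lower in 13 of 15 tumours, and these 2 of 32 differentiation genes passed adjusted over the list alone (limma adjusted p = 0.00436 and 0.00874) where 0 passed over all genes. KRTDAP differed by -1.35 and the alarmin subunit S100A8 by -2.02. KRT16, a keratin of hyperproliferative epidermis, fell by 0.87 with a limma adjusted p of 0.0332 adjusted over the list alone, the 1 such gene among 13 squamous carcinoma genes; MMP10, CDKN2A and MMP1 differed by -0.36, 0.15 and -1.32. Among 15 genes of epithelial-mesenchymal transition, VIM differed by -0.64, TGFBI by -0.21, ITGA5 by 0.26 and TWIST2 by 0.27, and 0 passed adjusted over the list alone. Other falls shrank less or grew without the 4 tumours with a compressed range. SPRR1B, SPRR2A, KRTDAP, S100A8, KRT16 and MMP1 differed by -0.60, -1.28, -1.29, -1.54, -0.84 and -1.67 there. ITGB1, VIM and TGFBI differed by -0.46, -0.48 and -0.16.

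Limma's camera placed 4 of these lists below the other genes: basal keratinocytes (adjusted p = 0.00384), keratinocyte differentiation (0.00384), squamous carcinoma keratins (0.0204) and epithelial-mesenchymal transition (0.0275). The calls were lost at adjusted p = 0.0669, 0.139, 0.164 and 0.287 with an estimated correlation, in the same order, and the sign-flip test of list shifts passed keratinocyte differentiation of these 4 (permutation p = 0.00507, adjusted over 29 lists 0.0490). Camera no longer passed squamous carcinoma genes without tumour 2, 5 or 12 (limma adjusted p = 0.0751, 0.0537 and 0.189), nor epithelial-mesenchymal transition without tumour 1, 11, 12 or 14 (0.0960, 0.0548, 0.0525 and 0.0808). Medians over members were -0.08, 0.03, 0.05 and -0.04, so that differentiation and squamous carcinoma genes had a median of the other sign than their mean. Without the 4 tumours with a compressed range, in which KRT5 was lowest, 0 of the 4 lists passed, with shifts of -0.03, -0.21, -0.15 and -0.07 against -0.28, -0.29, -0.26 and -0.12 over all tumours. With near-identical tumours also counted once they were -0.06, -0.31, -0.31 and -0.09, and 0 passed.

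Ribosomal protein genes had lower mean values in CD133-positive cells, with 21 of 24 measured members below 0. RPL30 was at 8.20 and 10.59 in CD133-positive and CD133-negative cells, RPS6 at 9.62 and 10.93 and RPL32 at 4.31 and 5.11; these 3 fell when adjusted over the list alone (limma adjusted p = 0.00574, 0.0474 and 0.00538), and 0 did over all genes. RPL23 differed by -0.33. The list's shift was -0.74 ± 1.44 (SD, n = 15), lower in 10 of 15 tumours, and limma's camera gave adjusted p = 1.16e-14, against adjusted p = 0.139 with an estimated correlation. Without the 4 tumours with a compressed range RPL30, RPS6, RPL32 and RPL23 differed by -1.37, -0.39, -0.70 and -0.02, the list's shift was -0.04 and the list did not pass (limma camera adjusted p = 0.760). Tumour 13 stayed in this set. Its CD133-positive array had RPL30 at 4.68, a difference of -5.77. Its list mean of 7.20 was the lowest of the 26 arrays without a compressed range.

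Genes of simple and glandular epithelium were higher in CD133-positive cells, and 21 of 22 measured members had a positive mean difference, where 73.3% of all genes did. The list's largest shifts were in tumours 1, 7 and 9, though not every member followed: KRT8 differed most in tumour 11, by 3.29. DCD, the antimicrobial peptide dermcidin of eccrine sweat glands, was at 11.31, 10.75 and 10.97 in the CD133-positive samples of tumours 1, 7 and 9 and at 6.14, 6.17 and 5.91 in their CD133-negative samples. SCGB2A2, the secretoglobin mammaglobin, was at 9.16, 9.71 and 9.68 there, against 3.88, 3.95 and 3.90. MUCL1, a small mucin-like protein, PIP, the prolactin-induced protein of apocrine glands, and KRT19 differed by 6.09, 2.92 and 3.32 in tumour 1. The chloride transporter SLC12A2, LTF, which encodes lactoferrin, and KRT7 differed by 6.08, 5.31 and 4.58 in the same tumour, and SLC12A2 and LTF by 1.78 and 0.76 in tumour 7. DCD was also at 10.25 in the CD133-positive sample of tumour 10, where PROM1 was at 3.32, and MUCL1 at 7.01 and 7.12 in tumours 3 and 8.

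The shift of the glandular list was 0.39 ± 0.70 (SD, n = 15) relative to all genes, higher in 12 of 15 tumours. Without tumour 1 the shift was 0.24 (limma camera adjusted p = 0.0343), and with near-identical tumours counted once the units other than tumour 1 and the pair of 7 and 9 had shifts of -0.06 to 0.18. Limma's camera gave adjusted p = 0.00384, lost at adjusted p = 0.498 with an estimated correlation, and all sign flips of the 15 tumours' shifts gave an exact two-sided p of 0.00281 (adjusted over 29 lists 0.0407). KRT18, a keratin of simple epithelia, rose by 0.44 with a limma adjusted p of 0.0156 adjusted over the list alone, the 1 such member, and was higher in 14 of 15 tumours; the mean over its several probe sets differed by -0.07. PIP, DCD and MUCL1 differed by 0.79, 1.33 and 1.16 on average, with SDs over tumours of 1.25, 2.16 and 1.91. Without the 4 tumours with a compressed range the list's shift was 0.53, and with dim genes filtered out camera's adjusted p was 0.0629.

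**Figure D3:**
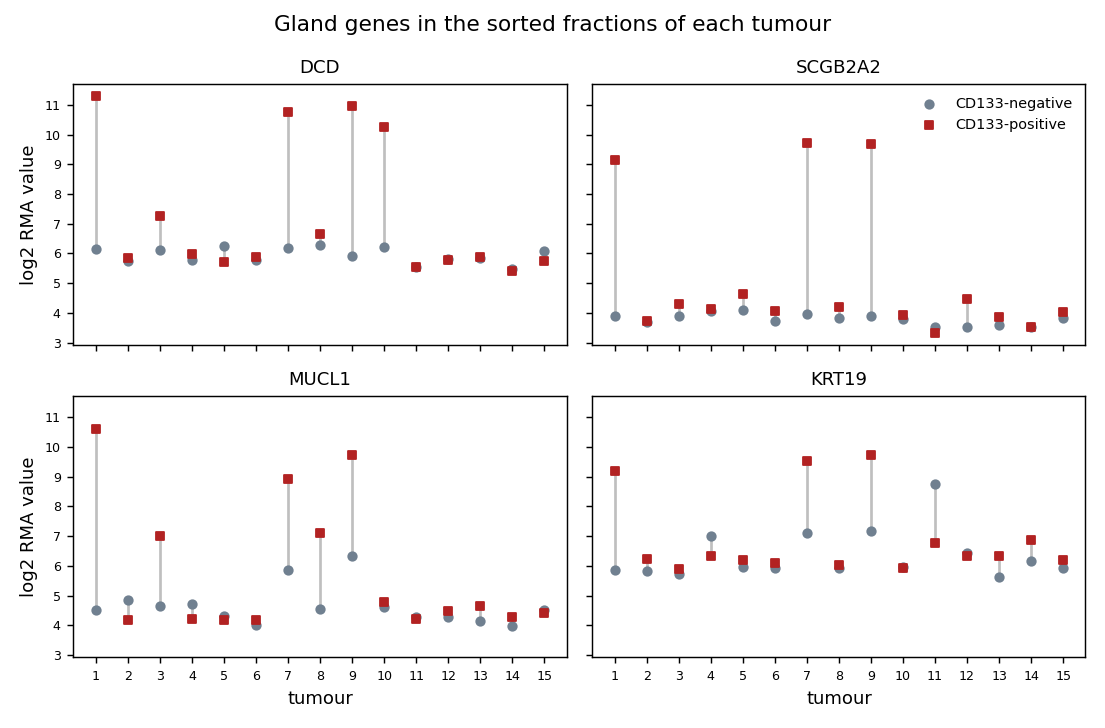
Log2 RMA values (vertical axes) of 4 gland genes, DCD, SCGB2A2, MUCL1 and KRT19, in the CD133-negative (circles) and CD133-positive (squares) sample of each of 15 tumours (horizontal axes), joined by a grey line. All 4 genes are higher in the CD133-positive samples of tumours 1, 7 and 9, with SCGB2A2 at 9.16, 9.71 and 9.68.

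Red blood cell genes were lower in CD133-positive cells, led by the globins. HBB was at 7.95 ± 2.76 in CD133-positive and 11.41 ± 0.69 in CD133-negative cells, a 10.9-fold lower geometric mean, and HBD at 4.69 ± 0.41 and 5.61 ± 0.58. Both fell when adjusted over the list alone (limma adjusted p = 0.000268 and 0.000215), 2 of 6 measured members, where 0 passed over all genes. The HBB difference was uneven, at -0.64 to 0.03 in tumours 2, 3, 6, 7, 8 and 9 and at -1.79 to -7.47 in the others. ALAS2, the erythroid enzyme of haem synthesis, differed by -0.37, SLC4A1, the band 3 anion exchanger, by 0.13, AHSP by -0.35 and the carbonic anhydrase CA1 by -0.07, and 0 of these 4 passed. AHSP differed by -4.45 in tumour 10 and by -0.63 to 0.56 in the others. CA1 differed by -1.53 in tumour 2 and by -0.37 to 0.48 in the others. The list's shift was -0.88 ± 0.73 (SD, n = 15), lower in 14 of 15 tumours; limma's camera gave adjusted p = 5.65e-06, against adjusted p = 0.0669 with an estimated correlation, and the exact sign-flip p was 0.00061 (adjusted over 29 lists 0.0177). The list also passed without the 4 tumours with a compressed range, with a shift of -0.94.

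Among markers of other skin and tumour cell types, the fibroblast list passed camera and the other 9 lists did not. Fibroblast genes were lower in camera (limma adjusted p = 0.00384, against adjusted p = 0.498 with an estimated correlation), with 14 of 20 members below 0, among them DCN at -1.07, COL3A1 at -0.58, SFRP2 at -0.27 and FAP at -0.20, and 0 members had an unadjusted p under 0.05 or passed limma's adjusted test. Without tumour 1, 12 or 13 the fibroblast list did not pass (shifts of -0.12, -0.17 and -0.16, limma adjusted p = 0.148, 0.0525 and 0.0508), nor without the 4 tumours with a compressed range (shift -0.17, limma adjusted p = 0.210). It passed without these and with near-identical tumours counted once (shift -0.30, limma adjusted p = 0.0169), and without tumour 10 its shift was -0.36, against -0.24 over all tumours. The shifts of endothelium, pericytes and smooth muscle, T and NK cells, B and plasma cells, myeloid cells, Langerhans and dendritic cells, mast cells, melanocytes and common leukocyte genes were 0.03, -0.04, 0.05, 0.03, -0.08, 0.04, 0.03, -0.07 and -0.01. Limma's camera gave adjusted p = 0.877, 0.885, 0.811, 0.862, 0.0927, 0.877, 0.877, 0.465 and 0.728 for them in the same order. Myeloid cells passed without tumour 6 (limma adjusted p = 0.0391). Camera's direction for mast cells was lower, against the sign of their mean. LYZ, the lysozyme of myeloid cells, differed by -1.20 and was lower in 12 of 15 tumours, the pericyte gene RGS5 by -0.35, XBP1 by 0.49, CD3E by 0.18, and SOX10, the transcription factor of melanocytes, by 0.24. SOX10 differed by 0.11, FAP by -0.32 and SFRP2 by -0.46 without the 4 tumours with a compressed range. LYZ differed by -1.58, RGS5 by -0.47, XBP1 by 0.43 and CD3E by 0.18 there. The shifts of Langerhans and dendritic cells and of common leukocyte genes had the other sign without those tumours (-0.02 and 0.00).

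The stem cell list did not separate the fractions, with a shift of -0.07 and a limma camera adjusted p of 0.656. Of its members 11 of 21 lay above 0, where 73.3% of all genes did. SOX9 was at 7.20 in CD133-positive and 6.91 in CD133-negative cells, higher in 12 of 15 tumours (limma adjusted p = 0.0585 adjusted over the list alone), and differed by 0.18 without the 4 tumours with a compressed range. The RNA-binding protein MSI1 differed by 0.24, the transporter ABCG2 by 0.12 and KLF4 by -0.22, and by 0.09, 0.07 and -0.14 without those tumours, where the list's shift was 0.02.

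Wnt pathway genes had 30 of 35 members above 0, where 73.3% of all genes were above 0. The leading members were WNT3 at 0.32, NKD1 at 0.29, WNT7A at 0.23 and ZNRF3 at 0.21. The list had a limma camera adjusted p of 0.0571, and adjusted p = 0.745 with an estimated correlation. The Wnt list passed camera with quantile normalization on top (limma adjusted p = 0.0253), with arrays centred on their median (0.0430), with near-identical tumours counted once (0.0319), and without tumour 3, 4, 6, 7, 9, 10 or 14 (0.0379 to 0.0467). It did not pass without the 4 tumours with a compressed range (shift 0.06, limma adjusted p = 0.197), where NKD1, WNT7A and ZNRF3 differed by 0.09, 0.14 and 0.07. For Hedgehog pathway, proliferation and interferon response genes camera gave adjusted p = 0.728, 0.728 and 0.622, with BOC at 0.15, CCNB2 at 0.24 and OAS1 at 0.26. Without those tumours BOC and CCNB2 differed by 0.09 and 0.13, and the Hedgehog shift of 0.03 turned to -0.01.

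Hypoxia and glycolysis genes and immediate-early and dissociation stress genes had shifts of -0.10 and -0.13 and a limma camera adjusted p of 0.0589 each, with DDIT4 at -0.70, NDRG1 at -0.41, HSPB1 at -0.37 and PPP1R15A at -0.49. With near-identical tumours counted once both passed (limma adjusted p = 0.0284 and 0.0101). Hypoxia genes also passed without tumour 1, 3, 7, 10 or 14 (0.0156 to 0.0430), and stress genes without tumour 1, 3, 7, 8, 9, 10, 11 or 15 (0.00861 to 0.0410). Both shifts had the other sign without the 4 tumours with a compressed range, at 0.05 and 0.09 (limma adjusted p = 0.959 and 0.553), and DDIT4 differed by -0.30. With array weights they were 0.02 and 0.00. The reference genes had a shift of -0.16 (limma camera adjusted p = 0.121), with B2M at -1.48 (-0.20 without the 4 tumours with a compressed range) and GAPDH at 0.40, and passed with near-identical tumours counted once (0.0129) and without tumour 3, 10 or 14 (0.0486, 0.0351 and 0.0379). Their shift also had the other sign without the 4 tumours (0.14, limma adjusted p = 0.330) and with array weights (0.07). Fry, limma's self-contained test, passed 0 of the 29 lists at an adjusted p under 0.05 for change in 1 direction, and its mixed test for change in either direction passed 1, keratinocyte differentiation (limma adjusted p = 0.00561).

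**Figure D4:**
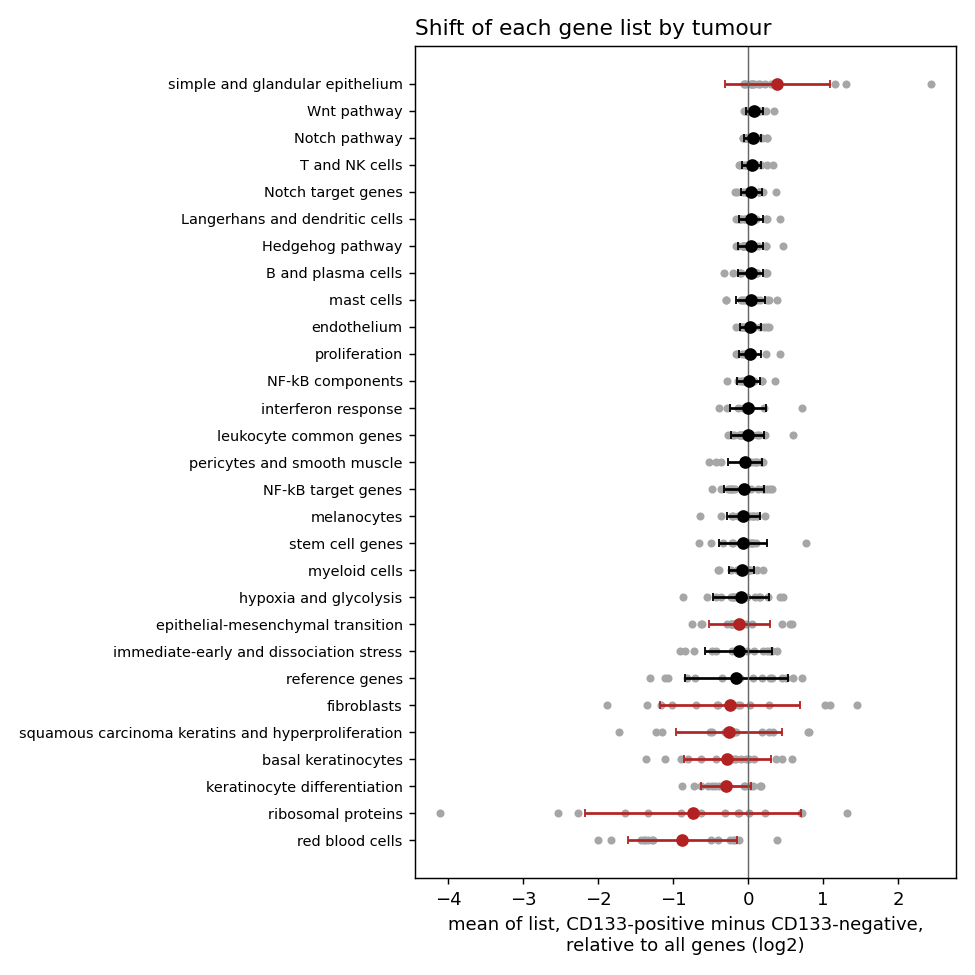
Mean paired difference of each of 29 gene lists relative to all genes (log2, horizontal axis); grey points are 15 tumours, large points their mean and bars 1 SD, in red where limma's camera with its preset correlation gave an adjusted p under 0.05. Red blood cells (-0.88) and simple and glandular epithelium (0.39) lie at opposite ends, and ribosomal proteins spread most across tumours.

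Of the variance over all genes, 56.4% lay between tumours and 5.77% between CD133-positive and CD133-negative samples, where 48.3% and 3.45% correspond to their degrees of freedom alone. The first principal component held 34.2% of the variance and had r = -0.75 with the SD of the array across 30 arrays.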

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

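The analyses without the 4 tumours with a compressed range, with near-identical tumours counted once, with both, and the sign-flip test of lists were chosen after the results were seen; the other alternatives were set before. Unless a construction is named, the cause of a change was not tested. PROM1 was higher in CD133-positive cells under every alternative that gave a value, but limma's p exceeded 0.05 with quantile normalization on top (difference 0.72), arrays centred on their median (0.75), without the 4 tumours (0.96), near-identical tumours counted once (0.79) and both (1.04), the last 3 testing fewer units. Leaving out 1 tumour gave 0.44 to 0.84. The count of genes, 0 with the paired block, was 5 with no replicate block, 11 with a random block, 5 with quantile normalization, 2 with dim genes filtered out, 5 with array weights, 1 without the 4 tumours, 3 at an adjusted p under 0.1, 1980 at an unadjusted p under 0.05, and 0 to 2 leaving out 1 tumour. It was 0 with median centring, the mean of probe sets, near-identical tumours counted once, both, the unmoderated and trend-robust tests, a 1.5-fold minimum and each probe set tested singly. The count of lists, 8 with camera, was 5 with dim genes filtered out, 3 with array weights, 2 without the 4 tumours, 13 with near-identical tumours counted once, 3 with both, 0 with an estimated correlation, 0 with fry's test of 1 direction, 3 with sign flips, and 5 (without tumour 12) to 13 (without tumour 3) leaving out 1 tumour. For the NF-kB targets the shift was -0.10 (passing) with dim genes filtered out, -0.10 (passing) with near-identical tumours counted once, and of the other sign with array weights (0.028) and without the 4 tumours (0.025); leaving out 1 tumour gave -0.076 to -0.019. The NF-kB component shift was -0.0099 counted once and -0.016 to 0.030 leaving out 1 tumour, with the other sign without tumour 11, 14 or 15. The glandular shift did not pass with dim genes filtered out (0.38), an estimated correlation (0.39) or fry (0.43), nor the red blood cell shift with an estimated correlation (-0.88) or fry (-0.84). Notch and NF-kB genes passing over the list alone, 0 with the paired block, numbered 1 with no block, 2 with a random block, 4 with quantile normalization, 1 with dim genes filtered out, and 0 to 3 leaving out 1 tumour. Signs turned for KRT18 with the mean of probe sets (-0.066), for RELA without the 4 tumours (0.035), with both (0.014) and over -0.050 to 0.055 leaving out 1 tumour, and for NFKB1 over -0.051 to 0.023. NOTCH1's paired relation turned to r = 0.45 with the list median, and its relation in CD133-positive samples to 0.22 without the 4 tumours, and fell to -0.14 given the reference genes; leaving out 1 tumour gave -0.52 to -0.40 and -0.82 to -0.58. CHUK's relation turned to 0.032 with the list median, 0.020 counted once and -0.30 to 0.053 leaving out 1 tumour. Single-gene alternatives were run for 32 genes: those always named except PROM1, the leading genes per direction and members that passed over the list alone. Of these alternatives, 743 gave the same direction and side of the threshold, 35 newly passed and 14 turned. The second deposited table and a further PROM1 probe set gave no value, since the table repeats the values and PROM1 had 1 probe set, and PROM1 was removed by the dim filter. No background level was estimated here, so levels near the floor, such as PROM1 in most samples and CHUK, were not separated from it.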

Other observations

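Tests of the compressed arrays, of near-identical tumours counted once and of gland cells were chosen after the results were seen; the counts of splits and the HBA1 and HBA2 test were set before their values were seen.

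SCGB1D2, a secretoglobin of glands, was at 7.62 in the CD133-positive and 3.59 in the CD133-negative sample of tumour 1, at 4.98 and 3.29 in tumour 9, and at 4.05 and 3.67 in tumour 7. Of the 22 measured glandular genes, 15 lay above the gene median of 4.58 in CD133-negative cells and 0 stood in another list; of the 6 red blood cell genes, 3 did and 0 stood in another list. AHSP, the chaperone of alpha haemoglobin, was at 8.09 in the CD133-negative sample of tumour 10 and at 3.63 in its CD133-positive sample, and ALAS2 was at 7.33 and 5.11 there. In the other 14 tumours the AHSP difference ran from -0.63 to 0.56.

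At an unadjusted p under 0.05, 4.05 genes were higher per gene lower in CD133-positive cells, and 80.2% of these genes were higher. Without the 4 tumours with a compressed range the ratio was 1.27, so the compressed arrays are a candidate explanation of most of the excess. With arrays centred on their median 1235 genes were higher and 523 lower, and with array quality weights 796 and 467. Splits that swapped the fractions within tumours were compared with the real split, which is counted among them. Chance could not be excluded for the number of genes, since 6 of 100 splits gave as many, with 1980 for the real split and 4547 for the highest other. Nor could it be for the 8 lists passing camera, since 10 of 100 splits gave as many, with 10 lists as the highest other. For the 0 genes at an adjusted p under 0.05 the comparison decides nothing, since all 100 of 100 splits must give at least as many, and the highest other was 0.

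Gland genes were higher in CD133-positive samples. Compressed arrays are argued against as the cause, since the shift was 0.53 without those tumours (exact sign-flip p = 0.00195, n = 11), as are near-identical arrays, since the exact sign-flip p was 0.0151 with them counted once (shift 0.36). Gland or duct cells in the CD133-positive fraction stay open: counted once, the 2 of 12 tumours with a PROM1 difference over 1 were also the first 2 in gland shift (exact chance 0.0152), but that number of tumours was chosen after both were seen, so the value decides nothing. Gland genes expressed by the tumour cells themselves would give the same pattern and were not tested, and the CD133 sort would not remove CD133-positive duct cells.

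Globin genes were lower in CD133-positive samples. The compressed arrays are argued against by a shift of -0.94 without those tumours (exact sign-flip p = 0.000977). Near-identical arrays are argued against by a shift of -0.96 counted once (exact sign-flip p = 0.00244). Over all tumours the shift was -0.88. These 2 p-values are unadjusted over the gene lists, and whether they would pass after that adjustment was not tested. Red blood cells in the CD133-negative fraction are a candidate explanation: the 2 probe sets shared by HBA1 and HBA2, which were outside the tested genes, differed by -2.50 ± 1.54 (SD, n = 15), from 11.18 to 8.68, lower in 14 of 15 tumours (exact sign-flip p = 0.000122). HBB was at 11.41 in CD133-negative and 7.95 in CD133-positive cells, and a sort for CD133 would leave red blood cells in the negative fraction unless they were removed before. In tumours 2, 3, 6, 7, 8 and 9, however, HBB differed by only -0.64 to 0.03, so both fractions held HBB RNA at similar levels there. PROM1 separated the fractions in tumours 7 and 9. AHSP, CA1 and SLC4A1 differed by -0.35, -0.07 and 0.13 and were lower in 10, 7 and 5 of 15 tumours, so free globin RNA, and a biological difference between the fractions, stay open.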
